A study of Arabidopsis thaliana with 6 samples.

How the data were processed

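Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole seedlings of Arabidopsis thaliana aged 15 days, grown in 12 h of light and 12 h of darkness at 70 µmol m-2 s-1 on Murashige and Skoog plates (agar at 0.8%, sucrose at 2%), per the labels' protocols. The protein studied was PRR7, a pseudo-response regulator of the circadian clock. Line 151 carries an HA-tagged PRR7 under the PRR7 promoter in the prr7-3 mutant, and untagged prr7-3 served as the control. Of the 6 samples, 2 were anti-HA immunoprecipitates (IPs) of HA-PRR7, 2 were anti-HA IPs of prr7-3, and each line had 1 input library. Lists of enriched regions from 3 samples were used: HA-PRR7 in experiments 1 and 2, and prr7-3 in experiment 1. The prr7-3 IP of experiment 2 was not analysed here. The time of day of harvest is not given in the sources used here, and nothing in the labels says that the experiments used separately grown plants.

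Reads were aligned with Bowtie to TAIR10, per the submitters' processing notes, which give no version. The peak caller, its settings and the library it used as control are not given in the sources used here. Regions were listed per sample, and nothing states that replicates were pooled. Each deposited list gives, for every region, the signal of the IP and of the control at the maximum, the ratio of the signals as a fold enrichment, whole-number counts of tags in both libraries, scores for the match between the strands, and -log10 p and q values, as the authors' caller wrote them. These scores and fold values are the authors' own and were used to describe, rank or filter regions within a list, to compare regions within experiment 1, and to correlate enrichment at shared regions between experiments, by rank and on the log2 scale. Tested on the values, the fold enrichment equalled the IP signal over the control signal, with the control raised to 1 where it was lower, in 100% of regions of each list within 1%.

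Depth per library was inferred from the lists, because they hold only enriched regions. The deposited tag enrichment was matched within 1% in 100% of regions by the IP tags over the larger of the scaled control tags and a uniform background over at least 300 bp. From this relation, a background window of 300 bp held 2.31 IP tags in HA-PRR7 experiment 1, 3.61 in prr7-3 experiment 1 and about 10.1 in list KC of experiment 2. The control held 15.4, 22.4 and 0.858 tags per window in the same order. Fold enrichments of experiment 2 therefore rest on 0 or 1 control tags in 86.1% of KC regions and 88.2% of TL regions, so a fold of one experiment is not on the scale of the other.

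HA-PRR7 in experiment 2 has 2 deposited lists, named KC and TL in the deposit, with no explanation of the letters. In 295 cases a region of one overlapped a single region of the other, and the reverse. Over these pairs the squared difference of IP tags divided by their sum averaged 1.08, where separate Poisson draws give 1 (upper chi-square p = 0.163), and region borders differed. In the 70 pairs whose widths matched within 2%, chosen after the data were seen, the average was 0.237 (lower chi-square p = 4.73e-12), though matching on width favours pairs with alike tags. Whether the lists share reads was left open, and since they belong to 1 sample they were counted as 1 replicate.

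Regions were called shared when they overlapped by at least 1 bp. A reproducible region was a region of HA-PRR7 experiment 1 that overlapped a region in each experiment 2 list and none in prr7-3. Shares carry exact Clopper-Pearson intervals (95%), which cover counting error only. Overlaps were compared with 1000 random placements of the regions on their own chromosomes (one-sided), and also with placements at the same distance from random genes. Enrichment was compared by permuting regions 100000 times (two-sided), and correlated between experiments across regions, which are not independent replicates. Gene lists were tested with Fisher's exact test (two-sided) against all 27444 protein-coding genes, with Benjamini-Hochberg adjustment over 9 lists of 183 genes in all. The lists, the rule for named genes and the other settings tried, except those named as later choices, were chosen before the data were examined. The named genes were every clock gene, members of other lists with a reproducible region, the 20 reproducible regions with the best worst rank over the 3 HA-PRR7 lists, the 5 highest prr7-3 regions, and the 5 highest experiment 1 regions shared with prr7-3. Other genes, such as list members with regions in experiment 2 alone, neighbours of a region and PIF5, were named after their values were seen.

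Several planned steps were changed because the only reference was a gene table of assembly TAIR10.1, with no sequence and no strand. The motif tests, including the G-box, were not run. Distance upstream of a transcription start was replaced by the share of summits between genes and within 1000 bp of a protein-coding gene. The plan was to assign each summit to the nearest transcription start within 3000 bp and, without a genome, to name regions by position only. Instead, a region was given the genes whose span holds its summit or, between genes, the nearest gene on each side within 3000 bp. This rule was chosen after the positions had been seen, and it raises the clock and light signalling counts: taking only the nearest gene would assign the CCA1 region to PSI-P and the LUX region to another neighbour, and the PHYB region to AT2G18780. All 5 assignments tried are reported. The table was used only for names and neighbours, and 176 of the list symbols matched it directly while 7 were matched by locus identifier. The files' TAIR10 positions fitted the table: 52.9% of reproducible summits lay between genes and within 1000 bp, against 13.2% to 27.9% after shifts of 5000 to 20000 bp. Coordinates are printed as the files give them, and whether they count from 0 or 1 is not stated. Mitochondrial regions were given no gene.

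Overlap and list tests were tested on simulated data. Of 50 simulated lists without shared regions, 8% gave p under 0.05 against list KC, and all 20 lists with 30 planted regions did (100%). Over the protein-coding genes, 0.222% of 900 null list tests were called, and the clock list was called in 100% of 100 runs with 5 planted members. The simulations drew positions and genes uniformly, as the tests assume. They therefore do not cover a preference shared by real lists, such as for places near genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.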

Results

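Anti-HA ChIP-seq lists from Arabidopsis seedlings were compared to find where HA-PRR7 was bound and which of these places recurred between experiments. HA-PRR7 had 685 regions in experiment 1 and, in experiment 2, 380 in list KC and 355 in list TL, which count as 1 replicate. Untagged prr7-3, the background for the antibody, had 143 regions in experiment 1. Regions of HA-PRR7 experiment 1 held a median of 10 IP tags (range 6 to 273), against 74.5 in KC, 75 in TL and 15 in prr7-3. Mitochondrial regions made up 25, 8, 6 and 8 of these lists in the order named.

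The comparison with untagged prr7-3 asked which HA-PRR7 regions were also called without the tag. Absence from the prr7-3 list shows only that no region was called in that IP, so such a region can still be background. No prr7-3 region held fewer than 11 IP tags, and the median region of HA-PRR7 experiment 1 held 10. These tag counts are not on the same scale. A background window of 300 bp held 3.61 IP tags in prr7-3 and 2.31 in HA-PRR7 experiment 1. The lowest IP signal in prr7-3 was 10.01, below the HA-PRR7 experiment 1 median of 11.57. The tag counts therefore do not show that prr7-3 missed such regions. Of the 685 regions of HA-PRR7 experiment 1, 8 overlapped a prr7-3 region (1.17%, interval 0.506% to 2.29%), none of them at a clock gene. They included 1 mitochondrial region and 5 nuclear regions within 1 Mb of the middle of the gene-poorest 2 Mb of their chromosome, where centromeres lie. The 5 with the highest enrichment were on chromosome 3 at 14201635 to 14201787 (11.5-fold), in AT4G25780 on chromosome 4 at 13121504 to 13121622 (5.69-fold), on chromosome 5 at 11683017 to 11683154 (4.82-fold), and on chromosome 3 at 13591900 to 13592098 (3.53-fold) and 13590189 to 13590318 (3.08-fold). The highest prr7-3 regions lay inside AT1G73160 (13.8-fold), AT3G23540 (12.8-fold), ESR1 (12.8-fold), the overlapping genes AT4G17243 and AT4G17245 (12.7-fold) and AT1G53440 (12.5-fold). Random placement gave 1.3 overlaps on average (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The share was 0.292% in the higher-enrichment part of the HA-PRR7 list (permutation p = 0.12). In its part with better q values the share was 1.51% (permutation p = 0.004). Without organelle and centromere regions it was 0.318% (permutation p = 0.022).

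Clock genes were among the highest regions found in both experiments. CCA1 and LHY, the MYB factors of the morning loop, PRR9, a relative of PRR7, and LNK3 (AT3G12320) and LNK2 (AT3G54500), members of a clock coactivator family, all had a region in experiment 1 and in both experiment 2 lists. In all, 70 of 685 experiment 1 regions (10.2%, interval 8.05% to 12.7%) overlapped both experiment 2 lists, and none of the 70 overlapped prr7-3. Of these reproducible regions, 68 were nuclear and 2 mitochondrial. Random placement gave 1.11 on average and at most 6 (one-sided permutation p = 0.001, the smallest possible), and placing the nuclear regions at the same distance from random genes gave 0.865 against 68 observed.

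The region between PSI-P and CCA1 (chromosome 2, 19245226 to 19245671) ranked 6 in experiment 1 with 26.7-fold enrichment and 82 IP tags, and ranked 1 in KC (125-fold) and in TL (128-fold). The PRR9 region (chromosome 2, 19232318 to 19232601) ranked 2, 3 and 3 in the 3 lists, with 33.4-fold enrichment in experiment 1. A region inside LNK3 (chromosome 3, 3923265 to 3923756) ranked 3, 5 and 4, with 31.9-fold enrichment in experiment 1. A region near BBX28 (AT4G27310), a B-box protein gene on chromosome 4 (13674856 to 13675245), ranked 5, 2 and 2. The LNK2 region ranked 20, 9 and 8. GI, a flowering and clock regulator, had 2 reproducible regions, which ranked 31 and 378 in experiment 1. Both overlapped the same experiment 2 region, which ranked 6 in KC and 5 in TL. LHY ranked 63, 14 and 14.

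Of the 20 reproducible regions with the best worst rank, 7 were at clock genes: PRR9, LNK3, CCA1, LNK2, GI, LHY and RVE7 (AT1G18330), a MYB factor related to CCA1. Others lay beside PHYB and AT2G18780, between AT5G15950 and AT5G15940, between SIGE and AT5G24130, between MSL5 and AT3G14820, beside OBP4, beside AGL44, near BBX29, between ERF38 and PGSIP7, beside MIPS1, and between AT1G27050 and ATHB54, and 1 was inside FER1, a ferritin gene. A further region, on chromosome 1 at 22184673 to 22184832, had no protein-coding gene within 3000 bp.

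**Figure D1:**
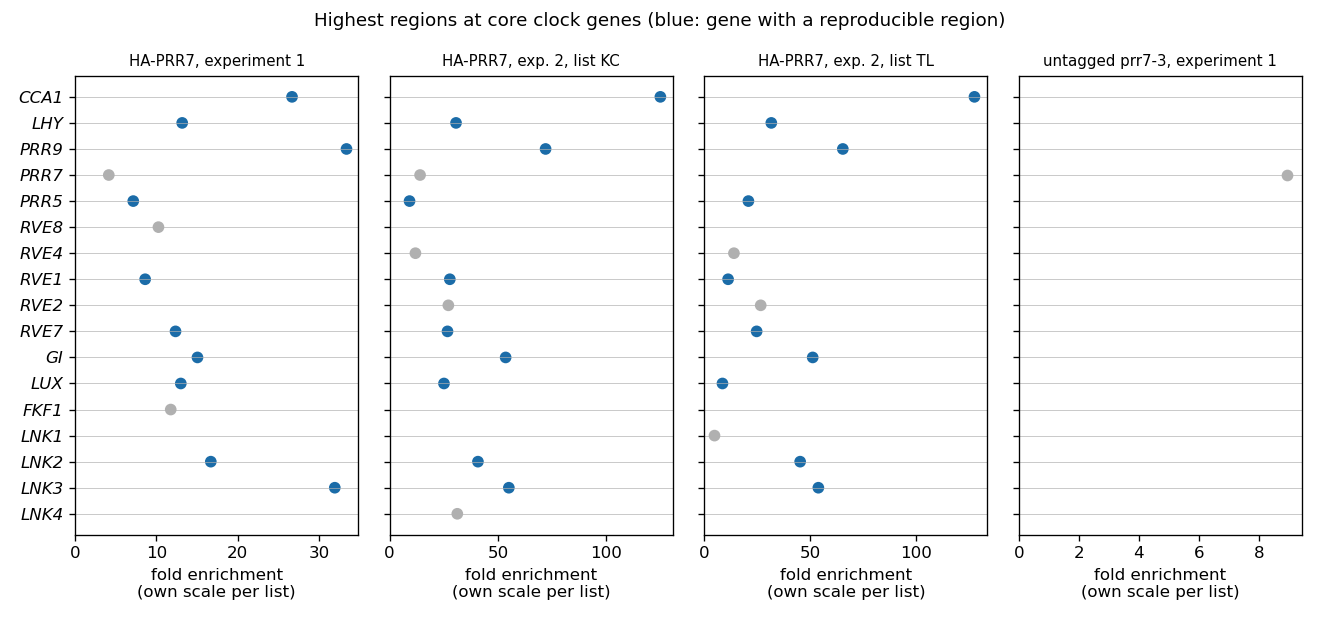
Fold enrichment (x axis, on a separate scale for each list) of the highest region at each core clock gene with a region in any list (y axis), in the HA-PRR7 lists and in untagged prr7-3; blue points mark the 10 genes with a reproducible region and grey points the other genes. CCA1 reaches 26.7 in experiment 1 and 125 and 128 in the lists of experiment 2, and PRR7 is the clock gene with a region in prr7-3.

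Of 28 core clock genes, 10 had a reproducible region: CCA1, LHY, PRR9, PRR5, RVE1, RVE7, GI, LUX, LNK2 and LNK3. The number of bound genes would give 0.104 by chance (Fisher's exact adjusted p = 3.57e-17), and random placement of the regions gave at most 3. The gene table places LUX, a component of the evening complex, beside a nearer neighbour. Assigning only the nearest gene within 3000 bp, which is closest to the planned rule, left 7 clock genes (Fisher's exact adjusted p = 3.1e-12), without CCA1, LUX and RVE1, and a limit of 1000 bp left 6 (adjusted p = 1.4e-10). A further 7 clock genes had a region in some list without a reproducible one. RVE8 and FKF1 had one in HA-PRR7 experiment 1, RVE4 and RVE2 in both experiment 2 lists, LNK4 in KC, LNK1 in TL, and PRR7 in experiment 1, KC and prr7-3. The other 11 had none in any list: TOC1, PRR3, AT5G52660, ELF3, ELF4, BOA, ZTL, LKP2, CHE, LWD1 and LWD2.

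Light signalling was the other list past the threshold among reproducible regions, with 3 of 32 genes (Fisher's exact adjusted p = 0.00103). These were PHYB, the main red-light receptor (ranks 10, 39 and 35), HY5, a bZIP factor of seedling greening (ranks 477, 20 and 19), and BBX24 (ranks 223, 32 and 33). AT2G18780 is nearer to the PHYB region than PHYB, and taking only the nearest gene within 3000 bp left 2 light signalling genes (Fisher's exact adjusted p = 0.012). Cold and dehydration had 1 of 22, CBF1, a cold-response activator (6.41-fold in experiment 1, Fisher's exact adjusted p = 0.236). No reproducible region was at any of the 24 abscisic acid signalling genes, 19 flowering-time genes, 24 photosynthesis and chlorophyll genes, 12 starch genes, 12 growth-hormone genes or 10 housekeeping genes (Fisher's exact adjusted p = 1 for each list). In prr7-3, PRR7 was the only member of the 9 lists with a region.

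**Figure D2:**
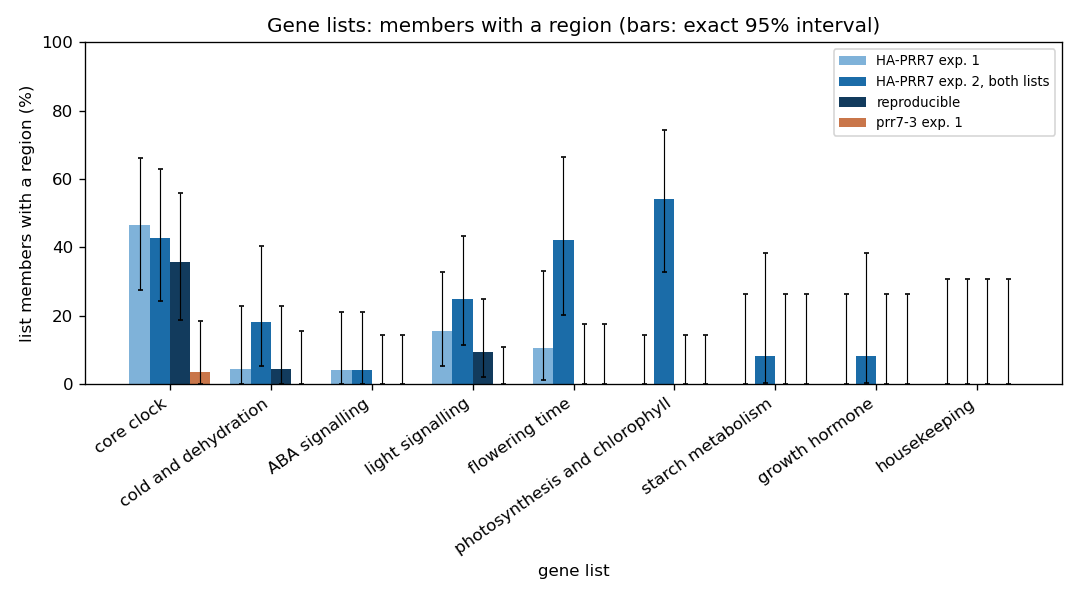
Percentage of the members of each gene list (x axis) with a region (y axis, %) in HA-PRR7 experiment 1, in both HA-PRR7 experiment 2 lists, in the reproducible set and in prr7-3 experiment 1, with exact 95% intervals as error bars. Core clock genes stand at 46.4%, 42.9%, 35.7% and 3.57%, while photosynthesis and chlorophyll genes stand at 54.2% in experiment 2 and at 0% in the other sets.

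In experiment 2, taken without experiment 1, 5 lists passed the threshold against all protein-coding genes: core clock, photosynthesis, flowering time, light signalling, and cold and dehydration. Core clock genes had 12 of 28 (Fisher's exact adjusted p = 1.16e-14). Photosynthesis and chlorophyll genes had regions in both experiment 2 lists in 13 of 24 cases (Fisher's exact adjusted p = 2.96e-17), including the light-harvesting genes LHCB1.1 (51.1-fold in KC), LHCB2.1 (29.3-fold) and LHCA3 (22.3-fold), and HEMA1, an early enzyme of chlorophyll synthesis (18.6-fold). None of the 24 had a region in HA-PRR7 experiment 1. Flowering-time genes had 8 of 19 in experiment 2 (Fisher's exact adjusted p = 4.55e-10), among them CDF1, CDF2, CDF3, COL1, COL2 and COL5, and 2 of 19 in experiment 1. Light signalling had 8 of 32 (Fisher's exact adjusted p = 4.01e-08), with PIF4, HYH, HFR1 and RUP2 among them, and 5 of 32 in experiment 1. Cold and dehydration had 4 of 22 (Fisher's exact adjusted p = 0.000522), namely CBF1, CBF2, CBF3 and GOLS3, and 1 of 22 in experiment 1. The genes named here outside the clock, apart from CBF1, were chosen after their values were seen. Each experiment has 1 HA-PRR7 IP, so these counts describe the libraries and show no difference between conditions. Neighbouring genes can share a region, as CBF2 and CBF3 do, and LHCB1.1 and LHCB1.3. Of 10 housekeeping genes, none had a region in both lists, though UBQ10 (11.8-fold) and GAPC1 (6.03-fold) had one in KC, while HAI1 was the 1 abscisic acid signalling gene, GBSS1 the 1 starch gene and BRI1 the 1 growth-hormone gene (Fisher's exact adjusted p = 0.341, 0.213 and 0.213).

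Regions in both experiment 2 lists, found in experiment 1 or not, lay beside genes more often than random placement gave, whereas most of those of untagged prr7-3 lay inside genes. Of 68 nuclear reproducible summits, 36 (52.9%, interval 40.5% to 65.2%) were between genes and within 1000 bp of a protein-coding gene, against 20.7% by random placement (two-sided permutation p = 0.002, the smallest possible). Of 227 regions in both experiment 2 lists without a match in experiment 1, 114 were (50.2%, against 20.4% by random placement), so this position is not particular to regions that recurred. The PRR9, CCA1, LHY, LNK2, LUX, GI and PHYB regions were of this kind, LNK3, RVE7, HY5, BBX24 and CBF1 held the summit inside the gene, and the PRR5 and RVE1 summits lay 1332 bp and 2351 bp from those genes. In prr7-3, 1 of 135 summits was between genes and within 1000 bp (0.741%), and 80.0% were inside a gene (interval 72.3% to 86.4%). The remaining 592 nuclear regions of HA-PRR7 experiment 1 were inside genes in 74.3% and between genes within 1000 bp in 11.3% of cases, below the 20.4% of random placement. Experiment 1 without its regions shared with prr7-3 stood at 15.8%, below chance (two-sided permutation p = 0.006).

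**Figure D3:**
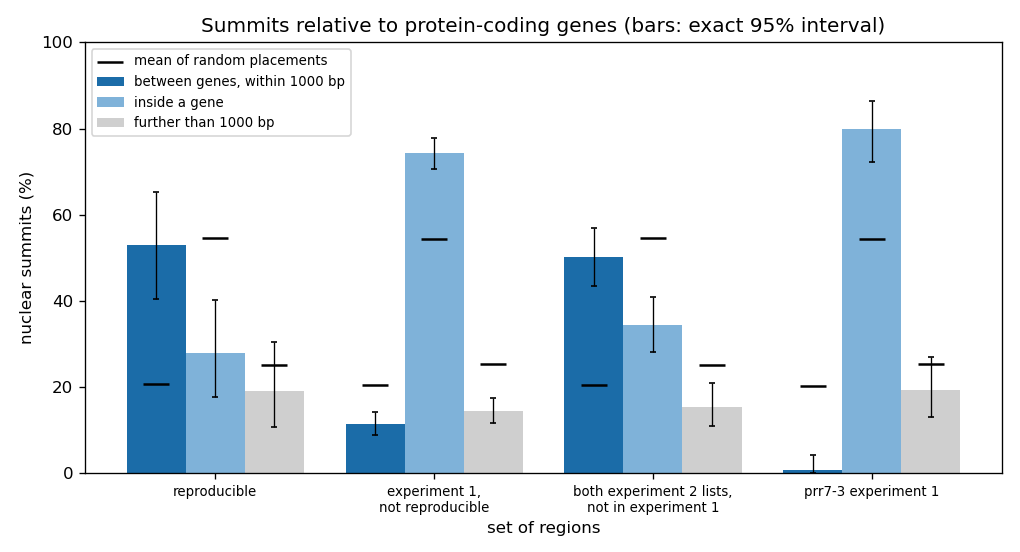
Percentage of nuclear summits (y axis, %) between genes and within 1000 bp of a protein-coding gene, inside a gene, or further away, for 4 sets of regions (x axis), with exact 95% intervals as error bars and the mean of random placements as black lines. Between genes and near 1, reproducible regions stand at 52.9% and experiment 2 regions not in experiment 1 at 50.2%, and prr7-3 regions at 80.0% inside genes.

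Regions found again were higher than the other regions of experiment 1. Their median enrichment was 12.0 (interquartile range 5.54, 70 regions) against 10.1 (4.20, 615 regions), a difference of 0.25 on the log2 scale (two-sided permutation p = 0.0011). Of the 20 highest regions of experiment 1, 14 were in both experiment 2 lists, including those at PRR9, LNK3, CCA1 and LNK2. Among the 6 found in neither was the highest of all, inside PIF5, a light-regulated growth factor gene (chromosome 3, 21830269 to 21830763), with 33.5-fold enrichment and 43 IP tags; it was singled out after its values were seen. In the fifth of nuclear regions with the most tags (12 to 82), 36.4% were reproducible (interval 28.2% to 45.2%), against 0.758% in the fifth with the fewest (6 to 8 tags, interval 0.0192% to 4.15%).

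**Figure D4:**
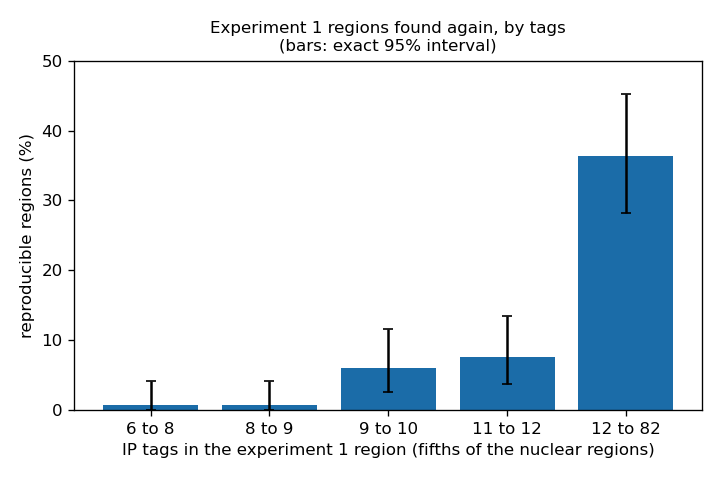
Percentage of nuclear HA-PRR7 experiment 1 regions that were reproducible (y axis, %) by the number of IP tags in the region (x axis, 5 equal groups of 132 regions), with exact 95% intervals as error bars. The share is 0.758% at 6 to 8 tags and 36.4% at 12 to 82 tags.

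Enrichment at the 70 reproducible regions was related between experiments, with CCA1, PRR9, LNK3 and BBX28 near the top of all 3 lists. Across regions, which are not independent replicates, Spearman's rho was 0.327 (permutation p = 0.0063, adjusted 0.0063) and Pearson's r of log2 enrichment 0.50 (p = 1e-05, the smallest possible, adjusted 2e-05). The 2 GI regions overlapped the same experiment 2 region, so its values enter more than once. Without the 2 regions farthest from the median of experiment 1, r was 0.454 (permutation p = 0.00012). Without the 10 regions highest in experiment 1, rho was 0.0959 (permutation p = 0.47) and r 0.238 (permutation p = 0.067), over a range narrowed by that choice. LUX ranked 34 in KC with 255 IP tags and 0 control tags, and 302 in TL with 263 IP tags, 1 control tag and a control signal of 3.71.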

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

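Taking only the nearest gene within 3000 bp, counting genes present in all 3 HA-PRR7 lists, leaving out the 10 highest regions, and other assignments for lists besides the clock were tests chosen after the data were seen. Of 74 values for the main results under other settings, 67 kept their direction and their side of the threshold or stayed within 1.5 times. With the higher-enrichment part of each HA-PRR7 list, the share of experiment 1 regions overlapping prr7-3 was 0.292% (permutation p = 0.12). With the part of better q values the share was 1.51% (permutation p = 0.004). In these parts 26 and 53 regions were reproducible, in that order, fewer regions entering by construction. Clock genes with a reproducible region ranged from 6 to 11 over 13 alternatives (adjusted p from 6.4e-19 to 1.4e-10): 6 with the nearest gene within 1000 bp, 7 with the nearest within 3000 bp, 8 with every gene within 1000 bp and 10 with genes in all 3 lists. The rank correlation without the 10 regions highest in experiment 1 was 0.0959 (p = 0.47; over all alternatives p from 0.00067 to 0.47), a choice that narrows the range and by itself lowers a correlation; other causes were not tested, and peak height gave 0.403. Leaving out each HA-PRR7 replicate in turn gave 296 to 677 regions and 12 to 13 clock genes. The share of summits between genes and near a gene ranged from 15.8% to 50.7%. The value without replicate 2, 15.8%, reversed to below chance (permutation p = 0.006). That set is mostly experiment 1 regions that were not found again, of which 11.3% lay there. Why those regions lay mostly inside genes was not tested. Of 120 values for the other gene lists, 104 were alike, 13 moved and 3 passed the threshold, all without replicate 1 (photosynthesis 13, flowering time 8, cold and dehydration 4 genes). Of the 4 other assignments, 3 gave light signalling 2 genes (Fisher's exact, adjusted p from 0.0082 to 0.016), and counting genes in all 3 lists gave 4 (adjusted p = 4e-05). Motif tests, gene bodies with 1000 bp upstream, and distances to transcription starts were not run for want of sequence and strand, and the correlation and the enrichment difference have no value with a replicate left out. No paired analysis was possible because the results are overlaps of region lists with no model over replicates, and only 1 prr7-3 IP had a list used here. Depth limits experiment 1, where calls rest on as few as 6 IP tags, and the control limits folds in experiment 2.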

Other observations

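Of the tests here, the count of housekeeping genes in both lists was fixed before its result was seen, and the counts in KC and TL alone and the tests of depth, the PRR7 locus, tag number, strand spacing and position inside genes were chosen after the pattern was seen. Beyond the fixed lists, reproducible regions named after their values were seen lay beside ELIP1, a light-stress protein gene, NF-YB2 and NF-YA4, subunits of a CCAAT-binding factor, and JAZ6, a jasmonate repressor gene. The region between DDB2 and cPT4 ranked 4 in experiment 1 and 4 in KC but 301 in TL. Its IP tags were alike in KC (260) and TL (261), and only the fold differed (63.6 and 9.12). The 2 mitochondrial reproducible regions ranked 630 and 672 in experiment 1.

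Photosynthesis genes had regions in both experiment 2 lists and none in experiment 1. Background at highly expressed genes, left in by the thin experiment 2 control, predicts regions at housekeeping genes too, if these are expressed as highly. In both lists, 0 of 10 had one against 13 of 24 photosynthesis genes (Fisher's exact p = 0.00487). Taken singly, KC had 2 (UBQ10 and GAPC1) against 13 (Fisher's exact p = 0.129) and TL 0 against 13 (Fisher's exact p = 0.00487). How highly the 2 sets of genes are expressed was not measured, so this comparison cannot weigh for or against background. A shallower experiment 1 library predicts that these regions are found again as often as others of similar height; 0 of 12 were, and over the 8 lists with regions the exact adjusted p was 0.025 matched on tag enrichment, 0.0212 on IP tags and 0.052 on fold enrichment, on a list singled out for this absence, so depth stays open. Summits of these regions lay inside genes in 8 of 12 cases against 88 of 282 for other experiment 2 regions (Fisher's exact p = 0.0224). In untagged prr7-3 of experiment 1, 80.0% of summits lay inside genes, yet none of the 24 photosynthesis genes had a region. That list had a denser control than experiment 2, and the position test was chosen after the pattern was seen. Neither value therefore weighs for or against background. Transcript levels were not measured and the untagged IP of experiment 2 was not analysed here, so background stays open. A difference in harvest or growth between the experiments stays open too.

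The PRR7 locus had 3 regions in HA-PRR7 experiment 1, all with high control signal (percentiles 98.6, 96.2 and 94.7 of the list). Additional copies of PRR7 in the transgenic input may account for this, if that input served as the control, which is not stated. Control tags per bp were 3.25 times the median nuclear region in HA-PRR7 experiment 1. They were 0.406 times in prr7-3, where the control signal stood at percentile 46.7. The high control signal was seen before the test, so it supplies a hypothesis only. Enrichment over the control was 3.04 to 4.14 in experiment 1, where the lowest of the list was 2.51, while KC had a region in PRR7 at 14.0-fold with 151 IP tags and 0 control tags, and TL had none. Untagged prr7-3 also had a region in PRR7 (8.94-fold, 17 IP tags), so binding of PRR7 to its own gene stays open.

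Most experiment 1 regions were not found in experiment 2. Calls close to the tag minimum of a shallow library may account for part of this, since the share found again differed between the fifth with the most tags and the fifth with the fewest (Fisher's exact p = 1.1e-15). Pile-ups at single sites predict a shorter spacing between strand peaks in the other regions, and the medians differed by 2 bp (44 against 42, permutation p = 0.37), which leaves that explanation undecided. Tag number leaves much uncovered: in the fifth with the most tags 84 of 132 regions (63.6%) were not found again, and PIF5, which ranked 1 in experiment 1 with 43 tags, had no region in experiment 2. No biological explanation was tested.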
